A study of Mus musculus with 6 samples.

How the data were processed

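The series measured RNA in sorted thymocytes of C57BL/6 mice, 4 wild type (WT) and 2 with a knockout of Tcf7 (KO), the gene of the transcription factor TCF-1. Per the labels' protocols, thymi were pressed through sieves and the double negative 3 (DN3) cells were sorted by the surface markers CD25 (present) and CD44, CD3, TCRβ, CD8, NK1.1 and CD1d tetramer binding (absent). RNA was purified from the lysed cells and amplified with a SMART-Seq v4 ultra low input kit, which does not mark the strand, and paired ends were read on a NextSeq instrument. The design text states that each sample came from an individual mouse. The labels give the sex of each mouse: WT 1, 2 and 3 and KO 2 were female, and WT 4 and KO 1 were male.

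The deposited values are raw counts per Entrez gene, made with featureCounts on the mm10 build, per the submitters' processing notes. The aligner, the versions and the strand setting are not given in the sources used here. The table of the whole series holds 26332 genes in 6 libraries, and the 6 tables of single libraries hold the same values. No count column was left unmapped. Gene symbols came from a RefSeq gene table of assembly GRCm38.p6, which is the mm10 primary assembly, by Entrez identifier: 25275 identifiers matched, 18 more were named from GENCODE tables, and 1039 had no symbol. Coordinates are those of that assembly. Because the library kit does not mark strand, reads of a gene and of an overlapping antisense gene cannot be told apart. Genes with near-identical copies (the T-cell receptor segments and constant regions, Hba-a1 and Hba-a2, Hspa1a and Hspa1b, class II genes, Gimap genes) may share or lose reads, and their values are less certain.

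The deposited counts were tested with edgeR 4.0.16 (R 4.3.3). Genes were kept by filterByExpr with its default count minimum of 10, by genotype, which left 13294 genes. Libraries were scaled with TMM factors, and a quasi-likelihood F-test with robust dispersion compared KO with WT in a model with sex as an additive term, leaving 3 residual degrees of freedom. Sex was included because both sexes occur in both genotypes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM values are counts scaled to a common library size after TMM scaling, means are given with the SD over the 4 WT libraries, and the KO libraries are given singly. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. For a gene with no count in a whole group, a fold is given as a lower bound against 3 counts over that group, with the counts of the other group pooled, and for a group with 1 to 3 counts as a ratio with its exact 95% interval. Intervals and floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules. A second model added the interaction of genotype and sex.

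31 gene lists were fixed before the data were examined, with 683 entries, of which 4 matched no gene and 12 matched by an older symbol. 30 lists were tested with camera of limma 3.58.1 at the preset correlation of 0.01, adjusted over the 30 lists. The same test with an estimated correlation and the rotation test fry were run beside it. With an estimated correlation camera works with the 3 residual degrees of freedom of the model, so few lists can pass. The list of sex-linked genes served only as a check of labels. Genes named in the text were chosen by a rule fixed at the same time. The rule names Tcf7 and Lef1, then the 12 largest changes in each direction and up to 4 members per list. The 12 had to pass the test, reach 5 CPM in the higher group, have both KO libraries outside the WT range, and have no clone, pseudogene or small RNA name. It also names all sort-gate and sex-linked genes, and the 3 genes with the smallest p in the interaction test. A few genes that the rule names are not reported here. Any other gene named is said to have been chosen after its values were seen.

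Depth was 41666797, 23711513, 25895530 and 28196671 counts in WT 1 to 4 and 19589938 and 13673860 in KO 1 and KO 2, so that 3 counts correspond to 0.072, 0.125, 0.115, 0.105, 0.154 and 0.224 CPM. Replicates were compared by a chi-square statistic over genes with at least 20 counts. Per degree of freedom it was 3.37 to 23.05 between WT libraries and 104.14 between the KO libraries, a value above 1 being certain for separate mice and amplified reads. Each library counts as 1 sample because each came from an individual mouse.

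The tests were tried on counts simulated for the KO against WT comparison, over 13294 genes with 200 changed. With one spread for both genotypes, edgeR recovered 61% of 2-fold and 87% of 4-fold changes and made 6 false calls among 154 calls. With the spread of each genotype as measured, it recovered 44% and 69%. It then made 345 false calls among 458 calls, 2.63% of the unchanged genes, so it did not hold its error rate. DESeq2 1.42.0 then made 1710 false calls among 1861. limma-voom with sample weights estimated per genotype made 19 among 86 and recovered 17% and 50%.

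Alternatives fixed before the data were examined were size factors as in DESeq2, upper-quartile factors, no low-count filter, a filter at 5 CPM in 2 libraries, DESeq2, limma-voom, no sex term, the replicate number as a block, females only, and each library left out. Added after seeing the data were limma-voom with weights per genotype and counts thinned to the smallest library. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The gene lengths in the tables were not used here.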

Results

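The data comprised 6 RNA-seq libraries of DN3 thymocytes, the stage of T-cell development at which the T-cell receptor β chain is rearranged and tested as part of the pre-T-cell receptor. The question, from the series title and design, was the part that Tcf7 plays in these cells, and the comparison was 2 KO mice against 4 WT mice. Total counts were 23711513 to 41666797 in WT, 19589938 in KO 1 and 13673860 in KO 2. Genes with at least 1 count numbered 15788 to 16013 in WT, 13294 in KO 1 and 14384 in KO 2. The first principal component of log2 CPM held 73.5% of the variance and had all 4 WT libraries on one side, between -36.1 and -32.7, with KO 1 at 79.3 and KO 2 at 57.3. The second held 21.8% and set KO 1 (40.6) apart from KO 2 (-50.3), with WT between 0.2 and 6.5.

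**Figure D1:**
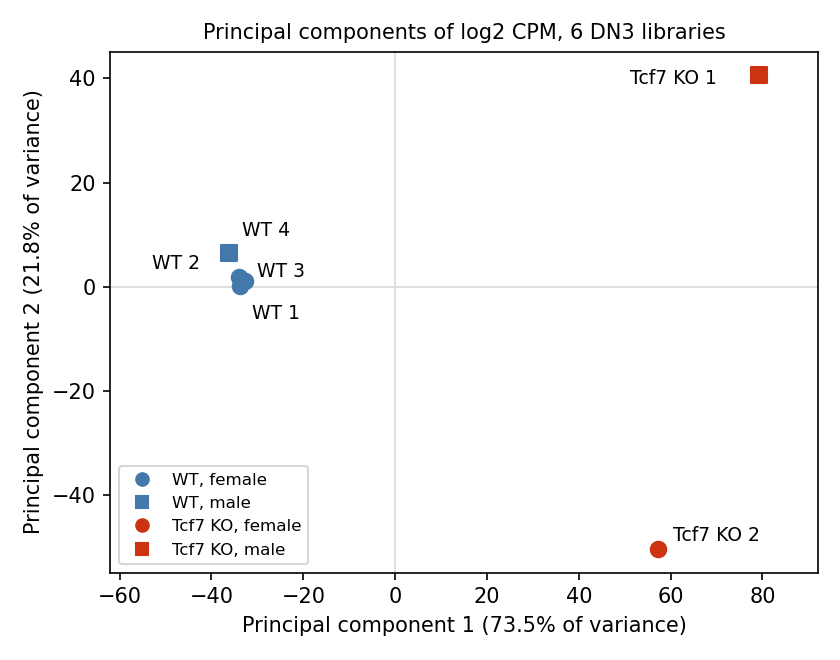
Principal components of log2 CPM over the 6 libraries, 1 point per library, with colour for genotype and shape for sex. The 4 WT libraries lie together, and the KO libraries lie apart from them on component 1 (73.5% of variance) and apart from each other on component 2 (21.8%).

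The labels were checked first on the targeted gene and on sex-linked genes. Tcf7 (Entrez 21414, chromosome 11, 52246527 to 52283383) stood at 2326, 2270, 2266 and 2094 CPM in WT 1 to 4 and at 1133 and 1022 CPM in KO 1 and KO 2. It fell by 1.05 on the log2 scale (SE 0.086, adjusted p = 0.00127), so its transcripts remained in both KO libraries at a reduced level. The labels do not say which part of the gene was removed, and counts per gene cannot show whether the remaining reads skip it. Xist, transcribed from the inactive X chromosome, was at 961 to 1327 CPM in the WT females, 607 in KO 2, 0.141 in WT 4 and 0.768 in KO 1. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty were at 107, 56.7, 85.0 and 50.5 CPM in WT 4 and at 73.4, 54.3, 52.8 and 32.9 CPM in KO 1. In the 4 female libraries each was at 0.145 CPM or less, and none of these 5 genes passed the genotype test. The list's other 2 genes, Tsix and Usp9y, had too few counts for a test.

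KO cells had higher levels of many mature T-cell genes and lower levels of many progenitor and immediate-early genes. In each of these lists some members did not pass or went the other way. As list calls these were lost (adjusted p = 0.172 with an estimated correlation for mature T-cell genes, 0.388 for each of the other lists). Lef1, the close relative of Tcf7 (Entrez 16842, chromosome 3, 131110297 to 131224357), rose 3.53-fold, from 264 CPM ± 36.1 (SD, n = 4) in WT to 860 and 902 CPM in KO 1 and KO 2 (log2 1.82, SE 0.094, adjusted p = 0.000402). Klf2, a factor that drives the exit of T cells from the thymus, rose from 2.92 CPM ± 0.573 to 195 and 239 CPM, and Cd2, an adhesion receptor of T cells, from 1.36 ± 0.409 to 199 and 233 CPM. Erg, a progenitor transcription factor, fell from 35.7 CPM ± 6.42 to 0.461 and 0.746 CPM, and Zeb2, a repressor, from 47.1 ± 0.705 to 1.33 and 1.49 CPM.

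Of 13294 genes tested with edgeR's quasi-likelihood test, 4076 (30.7%) differed at an adjusted p under 0.05, 1878 higher and 2198 lower in KO, and 2073 of them by at least 2-fold (960 higher, 1113 lower). In 3978 of the 4076, both KO libraries lay outside the range of the 4 WT libraries on the side of the change. This is no separate support, since the same 6 libraries gave the calls. In counts simulated with the spread of each genotype and 200 genes changed, 345 of 458 edgeR calls were false. The test thus did not hold its error rate at that spread, and the share of false calls among the 4076 is not known. 240 called genes had no count in either KO library, and 17 had none in any WT library. These 2 numbers cannot be compared directly, since WT had more libraries and each was deeper than either KO library. A group without a count is thus easier to reach in KO, and how much of the gap this accounts for was not tested. The KO libraries differed from each other far more than the WT libraries did (median biological coefficient of variation 0.386 against 0.0909), and limma-voom with weights per genotype, chosen after seeing the data, called 1500 genes (987 higher, 513 lower), of which 1404 were among the 4076. Leaving out 1 library gave between 1665 (without WT 1) and 9473 genes (without KO 2, with KO 1 assumed to vary like WT).

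The 12 largest rises were also ranked by edgeR's log2 fold change. Among them, Drd5, a dopamine receptor, Foxb1, a forkhead factor, and Tspan15, Thsd4, Prss32 and Xkr6 had no count in WT. Drd5 was at 61.6 and 2.69 CPM in KO 1 and KO 2, at least 1500-fold higher by pooled counts and at least 107-fold by KO 2 alone. By pooled counts Foxb1 (4.66 and 17.7 CPM) was at least 398-fold higher, Tspan15 (15.0 and 8.21) 490-fold, Thsd4 (25.9 and 3.51) 672-fold, Prss32 (7.83 and 4.03) 251-fold and Xkr6 (6.76 and 3.96) 224-fold. The smaller of the single-library bounds was 186 for Foxb1 (from KO 1), and from KO 2 it was 328 for Tspan15, 140 for Thsd4, 161 for Prss32 and 158 for Xkr6. Pdlim4, an actin-associated protein (chromosome 11, 54054928 to 54069032), rose from 0.154 CPM ± 0.0242 to 200.3 and 148 CPM (log2 10.02, SE 0.113, adjusted p = 1.25e-05), and Adam19, a membrane protease, from 0.569 ± 0.084 to 561 and 348 CPM (log2 9.48, SE 0.182, adjusted p = 3.12e-05). S100a4 rose from 0.0678 CPM to 4.55 and 58.8 CPM. Cd22, a B-cell receptor inhibitor, had 1 WT count in all and reached 6.29 and 25.2 CPM, a ratio of 1680 with an exact 95% interval of 300.0 to 66400. Dsg2 (3 WT counts; 0.819 and 35.2 CPM) and Rgma (2 WT counts; 4.45 and 23.4 CPM) completed the 12, with ratios of 592 (interval 201 to 2880) and 730.0 (201 to 6050).

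The 12 largest falls by edgeR's log2 fold change had no count in either KO library, so only lower bounds can be given and their rank rests on the zeros. A gene with a few KO counts can have fallen as much: the ratio for Fosb was 617 (exact 95% interval 171 to 5100). Arhgap32, a signalling protein, was at 36.0 CPM ± 0.846 in WT and at least 396-fold lower in KO. Btbd3 (15.5 CPM in WT) was at least 169-fold and Sytl4 (14.5 CPM) at least 160-fold lower. Ltbr, the lymphotoxin β receptor, Fnbp1l, Epb41l4a and Ptgs2, an inducible cyclooxygenase, were at least 117-, 113-, 105- and 102-fold lower. Ak4, Afap1l1, Ltbp3, Olfr1507 and Gab2 were at least 96.3-, 76.7-, 75.6-, 73.5- and 68.7-fold lower. With weights per genotype all 12 rises and 6 of the 12 falls kept an adjusted p under 0.05. In the simulation with the spread of each genotype, that test recovered 50% of 4-fold changes against 69% by edgeR. A lost call can thus also reflect low power.

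**Figure D2:**
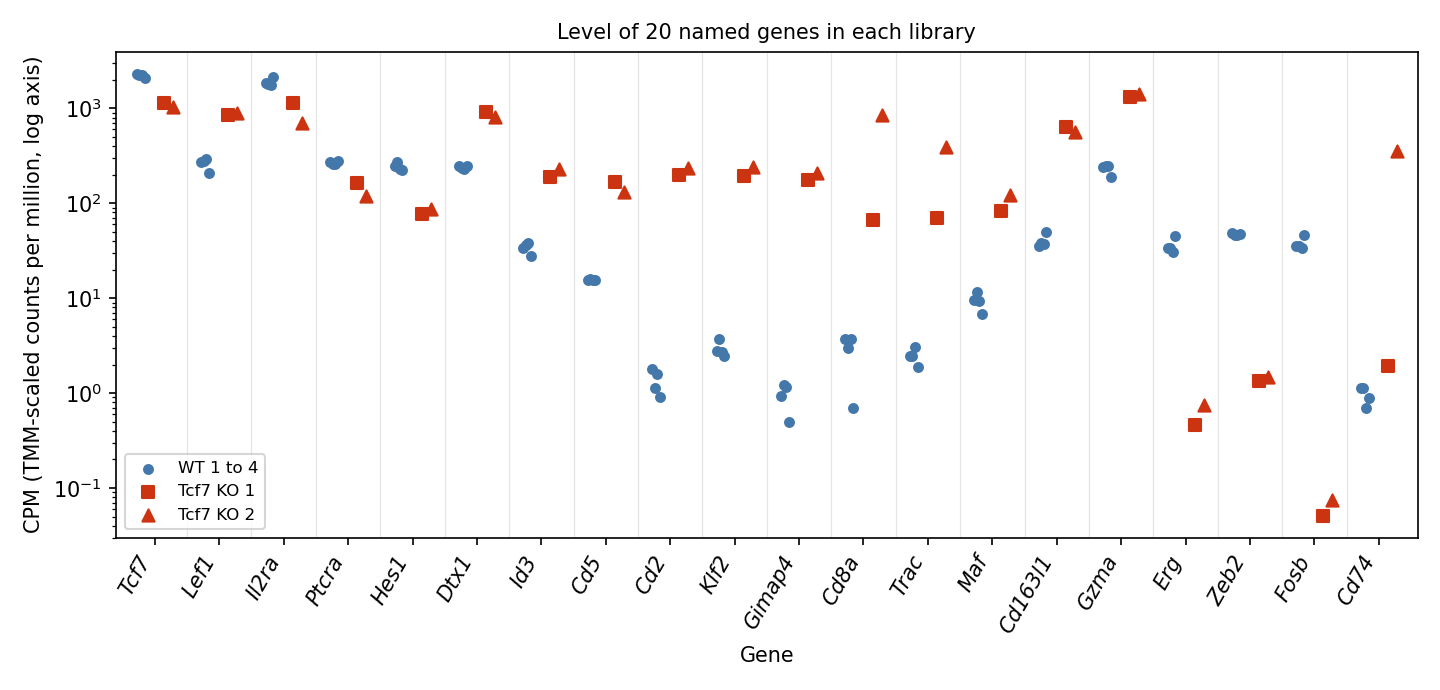
Level of 20 named genes in CPM on a log axis, 1 point per library, with WT in blue and the KO libraries in red (square, KO 1; triangle, KO 2). Klf2, Gimap4 and Cd2 lie close together in both KO libraries, while Cd8a, Trac and Cd74 differ between them (Cd8a 66.9 and 858 CPM).

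More T-cell identity genes rose than fell. Of 30 members, 17 rose and 3 fell (18 and 7 when adjusted over the list alone; camera adjusted p = 1.15e-11, adjusted p = 0.246 with an estimated correlation). Cd2 rose 169-fold, Cd7 28.3-fold, Cd5, a negative regulator of receptor signals, 9.34-fold (15.6 CPM ± 0.272 to 168 and 132) and Cd6 5.13-fold. In the list of mature T-cell genes, 13 of 19 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 1.1e-21, adjusted p = 0.172 with an estimated correlation). Gimap4 rose from 0.949 CPM ± 0.326 to 176 and 209 CPM (log2 7.82, SE 0.192, adjusted p = 5.98e-05), Klf2 rose 78.5-fold, and the integrin Itgb7 rose from 5.39 to 103 and 230 CPM. In the list of β-selection genes, which mark the passage out of DN3, 6 of 15 rose and 1 fell (7 and 2 adjusted over the list alone; camera adjusted p = 9.1e-05, adjusted p = 0.172 with an estimated correlation). Its examples were Id3, which restrains E proteins (34.1 CPM ± 4.75 to 190 and 227), Cd5, Cd27, a costimulatory receptor, which rose 2.33-fold, and the kinase gene Pim1, 1.42-fold.

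Genes of some surface proteins that the sort excluded were among those that rose. The gate read surface protein, whereas these values are RNA. WT cells from the same gate also held such transcripts, with Cd3g at 1428 CPM and Trbc2 at 384 CPM, so a rise alone does not show a failed sort. The list of sort-gate genes also holds Cd4 and Kit, which the stated sort did not use, so its counts and tests cover more than the gate. Of 12 sort-gate genes tested, 4 rose and 2 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.00534, adjusted p = 0.388 with an estimated correlation; 0.79 without KO 2, range 9.17e-10 to 0.79 over 16 alternatives). Cd8a (chromosome 6, 71373427 to 71379171) stood at 2.78 CPM ± 1.42 in WT and at 66.9 and 858 CPM in KO 1 and KO 2 (log2 7.67, SE 0.258, adjusted p = 0.000146), and Cd8b1 at 4.70 ± 2.20, 86.5 and 473 CPM. Trbc2, a constant region of the T-cell receptor β chain, rose 2.27-fold. Cd247 was 1.40-fold higher, with a call lost without WT 1, 2 or 3 (adjusted p = 0.119, 0.12 and 0.114) and with weights per genotype (0.157). Il2ra, which encodes the CD25 used for sorting, fell from 1881 CPM ± 164 to 1131 and 708 CPM, and Cd3g from 1428 ± 104 to 1078 and 757 CPM. Kit (65.2 CPM in WT; 1.08 and 22.5 in KO), Cd3e, Cd3d, Cd44, Cd4 (1.99 in WT; 0 and 12.8 in KO) and Trbc1 did not pass, and Klrb1c, the gene of NK1.1, had at most 5 counts in any library.

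In the double-positive list, for the stage that carries both CD4 and CD8, 8 of 20 rose and 4 fell (8 and 5 adjusted over the list alone; camera adjusted p = 9.1e-05, adjusted p = 0.388 with an estimated correlation). Without KO 2 its direction turned (adjusted p = 0.762; 5.68e-22 to 0.762 over 16 alternatives). Its examples were Cd8a, Cd8b1, Trac, the α chain constant region (2.47 CPM ± 0.477 to 69.5 and 394), and Ikzf3 (21.4 ± 2.74 to 370.0 and 346). In the list of chemokine receptors and homing genes, 8 of 15 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 9.1e-05, adjusted p = 0.388 with an estimated correlation; 0.518 without KO 2, range 6.82e-17 to 0.518). S1pr1, the receptor for thymic exit, rose from 0.198 CPM ± 0.108 to 21.8 and 84.0 CPM. Itgb7 rose 32.4-fold, Itgae, an integrin of CD8 and epithelial-homing cells, 8.85-fold and Ccr7 12.4-fold. KO 2, without which the list call was lost, also held B-cell transcripts.

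In the pre-T-cell receptor and rearrangement list, 3 of 18 members rose and 5 fell (3 and 5 adjusted over the list alone), and the list was not called (camera adjusted p = 0.92). Ptcra, the pre-T-cell receptor α chain, fell from 267 CPM ± 10 to 165 and 121 CPM and Cd3g fell, while the ligase Lig4 rose 1.98-fold and Trbc2 rose. Of 18 Notch targets, 3 rose and 7 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.153, not called, but lower by fry with adjusted p = 0.00293). Hes1 fell from 243 CPM ± 23.4 to 76.7 and 86.5 CPM, Cdk6 from 305 ± 12.4 to 56.6 and 68.4 CPM, and Notch3 from 1241 ± 114 to 789 and 730.0 CPM. Dtx1 rose instead, from 241 ± 8.63 to 922 and 808 CPM. Of 13 E-protein and Id regulators, 2 rose and 5 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.871, with a median of -0.30 and a direction of rise). Id3 rose 6.51-fold, while Ptcra, Tcf4 (81.6 CPM to 55.9 and 54.6) and Gfi1 (125 CPM to 97.9 and 93.4; call lost without WT 1, 2 or 3, adjusted p = 0.0624, 0.0596 and 0.0603) fell.

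Wnt and β-catenin targets, which TCF-1 and LEF-1 can bind, gave 5 rises and no fall among 10 members (6 and 0 adjusted over the list alone; camera adjusted p = 0.000333, adjusted p = 0.172 with an estimated correlation). Lef1 is itself a member, Tnfrsf19 rose from 0.888 CPM ± 0.338 to 30.4 and 23.5 CPM, the ubiquitin ligase gene Rnf43 from 0.638 to 5.32 and 14.9 CPM, and Apcdd1 2.24-fold. In the interleukin-7 and STAT5 list, 3 of 18 rose and 4 fell (3 and 5 adjusted over the list alone), and the list was not called (camera adjusted p = 0.773). Il2rb, a receptor chain for interleukins 2 and 15, rose from 0.868 CPM ± 0.265 to 20.4 and 25.8 CPM, while Il2ra, Bcl2, a survival gene (155 ± 6.78 to 70.6 and 79.7), and Trgc1 fell.

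More of the tested progenitor genes fell than rose. Of 14 members, 7 fell, 2 rose and 5 did not pass (8 and 2 adjusted over the list alone). The list was called lower by camera (adjusted p = 9.75e-05), but the call was lost with an estimated correlation (adjusted p = 0.388). Hoxa7 stood at 14.1 CPM ± 1.74 in WT and had 1 count in the KO libraries, a ratio of 474 (exact 95% interval 84.9 to 18700), Nfe2 fell 9.85-fold, and Erg and Bcl2 fell as well. In the list of T-cell leukaemia genes, 4 of 14 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.799). Zeb2 fell, while Lef1, Lyl1, a factor of early progenitors (0.294 CPM in WT; 24.9 and 5.45 in KO), and Cdkn2a, a cell cycle inhibitor (0.0688 CPM; 35.7 and 2.09), rose. Of 18 immediate-early and stress genes, 11 fell and 3 rose (11 and 4 adjusted over the list alone; camera adjusted p = 6.91e-05, adjusted p = 0.388 with an estimated correlation). Fosb, at 37.6 CPM ± 5.94 in WT, had 2 counts in KO, a ratio of 617 (interval 171 to 5100). The heat shock gene Hspa1b fell from 102 ± 77.1 to 5.02 and 2.54 CPM, Hsph1 2.22-fold and Dusp1 3.00-fold. WT 4 stood apart for Hspa1b (217 CPM against a mean of 63.4 in the other WT libraries) and Fosb (46.4 against 34.6), and the share of counts from the mitochondrial genome, also lower in KO, was 2.61 to 2.92% in WT, 0.893% in KO 1 and 1.78% in KO 2.

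Innate and γδ T-cell lists were called higher, but none of these calls held without KO 2, the library that also held B-cell transcripts. With sex in the model, the fit without KO 2 compares KO 1 with WT 4 alone, the only males. A call lost there can thus also reflect that small comparison or WT 4 itself. A link between these calls and the B-cell transcripts was not tested. The γδ call was also lost with limma-voom, and the group 2 call held in only 8 of 16 refits. In the type 17 list, 9 of 18 rose and 5 fell (10 and 6 adjusted over the list alone; camera adjusted p = 7.07e-05, adjusted p = 0.172 with an estimated correlation; 0.203 without KO 2, range 5.08e-07 to 0.203). Maf rose from 9.42 CPM ± 1.99 to 82.0 and 122 CPM (log2 3.58, SE 0.113, adjusted p = 0.000113), Irf4 16.6-fold, Batf 5.84-fold and Cd163l1, a scavenger receptor of γδ T cells, from 40.1 ± 6.63 to 630.0 and 570 CPM. Of the list's 25 members, 18 were tested. Among the untested, Il17a, the cytokine of this programme, had no count in any library, and Il17f and Il23r had at most 3. Ccr6, untested as well, had 115 counts in KO 2, 0 in KO 1 and 1 in WT. These untested genes were chosen after their values were seen. Receptor genes of the γδ list did not all rise. Trgc1, a γ chain constant region, fell from 409 to 424 CPM in WT to 227 and 201 CPM in KO 1 and KO 2. Trdc, the δ chain constant region, did not pass (302 to 341 CPM in WT, 22 in KO 1 and 298 in KO 2). Trdv4, a δ chain V segment chosen after its values were seen, was not tested. It had 253 KO counts, 246 of them in 1 library, and 16 WT counts. In the γδ list, 7 of 19 rose and 1 fell (7 and 2 adjusted over the list alone; camera adjusted p = 2.14e-05, adjusted p = 0.172 with an estimated correlation; 0.482 without KO 2, range 1.12e-08 to 0.482; median log2 change 0.016), with Cd163l1, Id3, Maf and Trgv1 (3.09-fold) as examples. The group 2 innate lymphoid list had 5 rises and 3 falls among 11 (5 and 3 adjusted over the list alone; camera adjusted p = 0.0381, adjusted p = 0.342 with an estimated correlation). Ptpn13 rose 12.7-fold, Il9r 13.8-fold and Pdcd1 3.21-fold, and Hes1 fell. Only 11 of the list's 22 members were tested. Among the untested, Il5, Areg and Arg1 had 0 counts in KO, while Klrg1 had 20 and Il1rl1 4, these genes being chosen after their values were seen. Without KO 2 the adjusted p of that list was 0.299 (range over the alternatives 0.00555 to 0.334).

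In the NK-cell list, 5 of 12 rose and 1 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.00368 with a direction of rise and a median of -0.13; adjusted p = 0.409 with an estimated correlation; 0.728 without KO 2, range 0.000259 to 0.728). Gzma, a granzyme, rose from 231 CPM ± 28.9 to 1333 and 1407 CPM, Il2rb 29.8-fold, Prf1 from 0.315 to 2.15 and 10.5 CPM and Nfil3 6.40-fold. Only 12 of the list's 26 members were tested, and its call was also lost with limma-voom. Among the untested, Ncr1, Klrb1c and Eomes had at most 1 count in either KO library. Klrd1 reached 27 and Ccl5 66 counts in a KO library. These untested genes were chosen after their values were seen. The invariant NKT list was not called (3 of 11 rose and 2 fell, 3 and 2 adjusted over the list alone, camera adjusted p = 0.0753). Il2rb and Sh2d1a (2.55-fold) rose, and Ifng, with 3 KO counts, was lower by a ratio of 20 (interval 6.74 to 97.6; call lost without WT 1, 2 or 3, adjusted p = 0.0891, 0.0834 and 0.0629). Cxcr6 passed but was above WT (0.396 CPM) only in KO 2 (0.153 and 14.3 CPM in KO 1 and KO 2), and its call was lost without WT 1, 2 or 3 (adjusted p = 0.136, 0.124 and 0.124) and turned direction without KO 2 (log2 -0.20, adjusted p = 0.901). The interferon list had 13 rises and no fall among 29 (16 and 0 adjusted over the list alone; camera adjusted p = 4.25e-06, adjusted p = 0.558 with an estimated correlation; 0.728 without KO 2, range 5.26e-25 to 0.728). Its median log2 ratio was 0.037 in KO 1 and 1.88 in KO 2, the library that also held B-cell transcripts. Usp18 rose 6.25-fold, Oas2 5.02-fold, Oas1a 4.45-fold and Oasl2 3.54-fold.

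Markers of other cell types were unevenly spread over the KO libraries. Of 20 B-cell genes, 13 rose and none fell (13 and 0 adjusted over the list alone; camera adjusted p = 9.1e-05, adjusted p = 0.409 with an estimated correlation; 0.289 without KO 2, range 8.8e-30 to 0.289). Ighm rose 3.52-fold (208 CPM ± 16.1 to 522 and 877), and Cd79a stood at 0.117 CPM in WT and at 3.68 and 40.4 in KO 1 and KO 2. In the dendritic-cell list, 3 of 12 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.997, direction of fall with a median of -0.01 and a mean of 1.03; 0.0396 without KO 2, range 4.82e-08 to 0.988). Cd74, of the class II pathway, was at 0.958 CPM in WT, 1.95 in KO 1 and 359 in KO 2, H2-Aa at 0.360, 0.0512 and 108 CPM, Ccr7 rose and Tcf4 fell. Without WT 1, 2 or 3 the calls of Cd74 (adjusted p = 0.081, 0.0766 and 0.073) and H2-Aa (0.144, 0.136 and 0.137) were lost, as they were without KO 2 (log2 1.13 and -2.95, the latter from 1 count). The myeloid list was not called (1 of 11 rose and 2 fell, 1 and 3 adjusted over the list alone, camera adjusted p = 0.536). Itgam rose to 4.81 and 6.87 CPM, Lyz2 fell from 17.4 CPM ± 0.8 to 0.153 and 1.19 CPM, Cebpb fell from 22 CPM to 0.972 and 4.18 CPM, and Cebpa did not pass. The log2 change of Cebpb was -3.14, -4.67 without KO 2, -2.33 without KO 1 and -2.34 without WT 4, and its call was lost without WT 1 (adjusted p = 0.056; range 3.63e-17 to 0.112). The thymic stromal list was not called either (2 of 7 rose and 2 fell, 2 and 2 adjusted over the list alone, camera adjusted p = 0.56), though fry called it lower (adjusted p = 0.0226): Epcam fell 3.05-fold, Cdh5 fell, Pdgfrb rose from 63.9 CPM to 773 and 226, and Pecam1 rose 1.21-fold. Without WT 1, 2 or 3 the calls of Cdh5 (adjusted p = 0.0604, 0.0669 and 0.0677) and Pecam1 (0.0926, 0.112 and 0.112) were lost. Of 9 erythroid genes, 3 rose (3 adjusted over the list alone; camera adjusted p = 0.0312, adjusted p = 0.409 with an estimated correlation; 0.621 without KO 2, range 0.0122 to 0.621): Hemgn rose 39.9-fold, and Tfrc did not pass. Hba-a1 (2.62 CPM in WT; 1.64 and 9.18 in KO 1 and KO 2) and Hba-a2 (1.66; 0.819 and 6.72), whose reads may be shared, passed with log2 values of 1.40 and 1.35. Both lost the call without WT 1 (adjusted p = 0.059 and 0.135), WT 2 (0.0584 and 0.133) or WT 3 (0.0569 and 0.128), and Hba-a2 also without KO 2 (log2 0.53, adjusted p = 0.449); over all alternatives adjusted p reached 0.914 and 0.929.

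Some mitotic genes rose. Of 40 genes of G2 and M phase, 15 rose, none fell and 25 did not pass (23 and 0 adjusted over the list alone; camera adjusted p = 3.71e-06, adjusted p = 0.579 with an estimated correlation, 0.066 by fry), with rises of Cenpf 2.92-fold, Ccnb2 2.82-fold, Cenpa 3.35-fold and Anln 2.10-fold. Their median log2 ratio was 1.39 for KO 1 against WT 4 and 0.35 for KO 2 against WT 1 to 3. The references differ, and WT 4 was the lowest WT library for Cenpf (43.1 CPM against 61.5 to 62.8), Ccnb2 (49.0 against 63.3 to 67.0) and Anln (24.4 against 33.7 to 38.4). Of 35 S-phase genes, 6 rose and none fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.00534, adjusted p = 0.672 with an estimated correlation; 0.468 without KO 1 and 0.529 without WT 4, range 2.64e-11 to 0.529), with Ccne1 at 2.61-fold, E2f8 at 2.07-fold, Rrm2 at 1.75-fold and Brip1 at 1.60-fold. The call of E2f8 was lost without WT 1 or 2 (adjusted p = 0.0574 and 0.0515) and that of Rrm2 without WT 1, 2 or 3 (0.062, 0.0643 and 0.0548). MYC and ribosome biogenesis genes fell in 11 of 33 cases and rose in none (11 and 0 adjusted over the list alone; camera adjusted p = 0.00534, adjusted p = 0.672 with an estimated correlation; 0.771 without KO 2, range 9.94e-09 to 0.771). Odc1 fell 1.85-fold, Nop58 1.65-fold, Ddx21 1.44-fold and Wdr43 1.36-fold (call lost without WT 3, with an adjusted p that rounds to 0.05).

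Among 27 p53 targets, 8 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.0143, adjusted p = 0.246 with an estimated correlation; 0.0654 without KO 1, range 0.000275 to 0.0675). Zfp365 rose 12.5-fold, the death receptor gene Fas 6.70-fold and Ddit4 3.52-fold, whereas Cdkn1a, the p21 cell cycle inhibitor, fell from 78.9 CPM ± 2.43 to 22.6 and 12.4 CPM. Of 20 apoptosis regulators, 11 rose and 2 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.00908, adjusted p = 0.246 with an estimated correlation). Casp8 rose 2.07-fold and Cflar, which restrains it, 1.72-fold, while Bcl2 fell 2.01-fold. In all, camera called 18 lists higher and 3 lower, fry 15 higher and 4 lower (progenitor, immediate-early, Notch and stromal genes), and camera with an estimated correlation none.

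**Figure D3:**
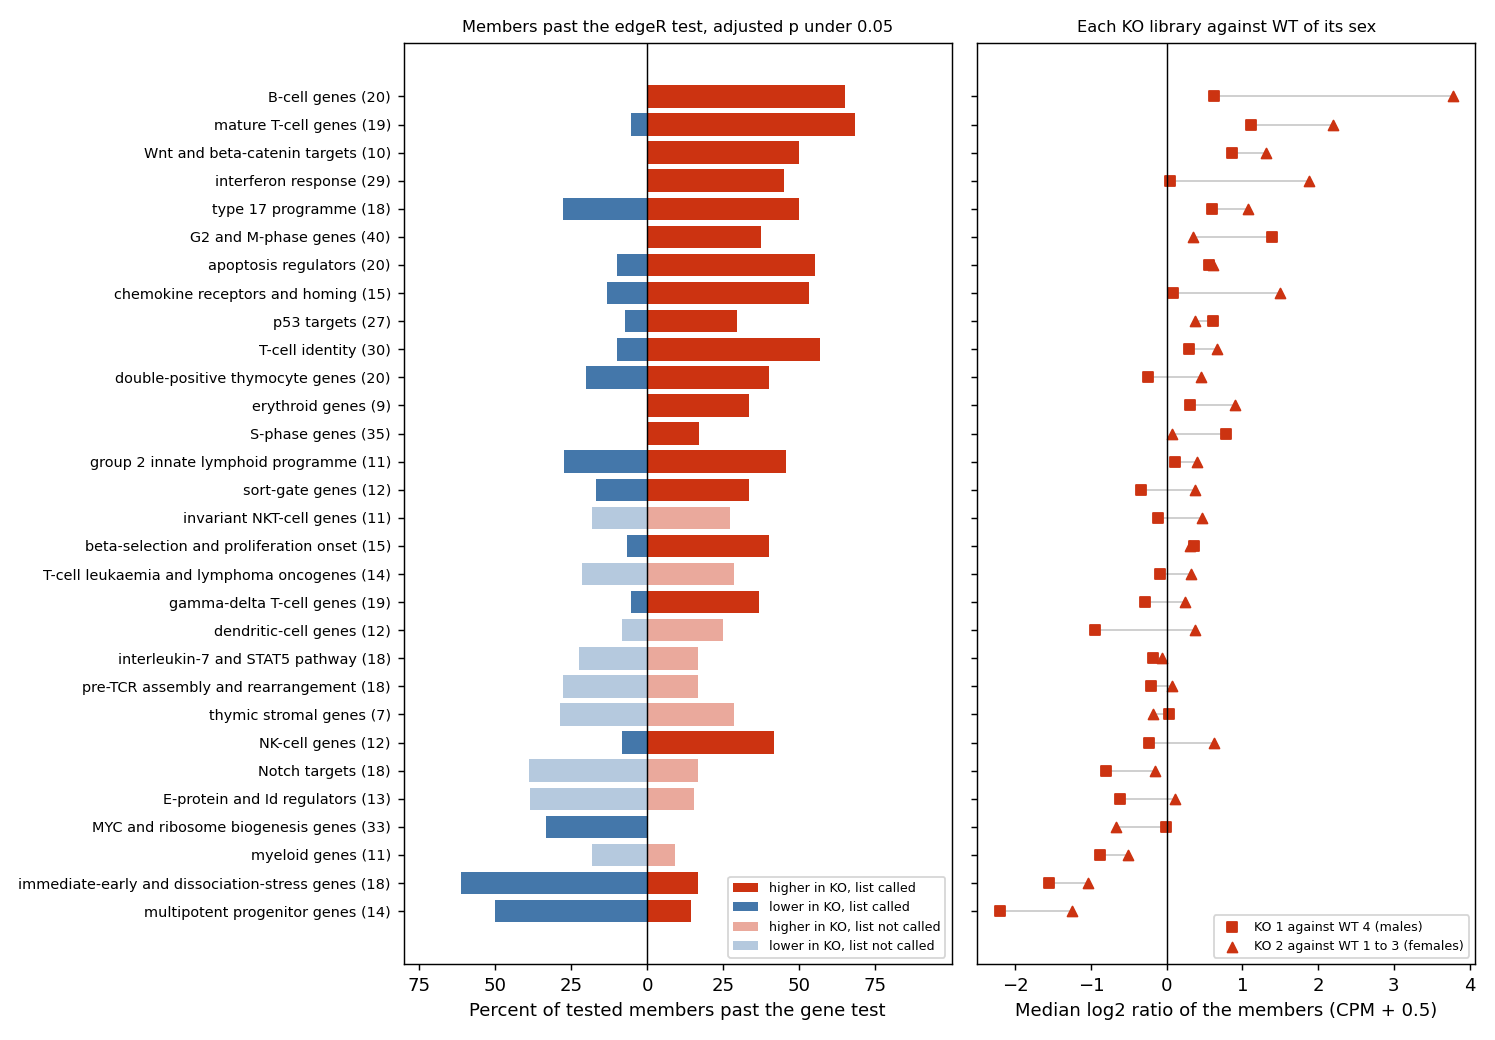
Left, the percent of tested members (number in brackets) of each list that were higher (right of 0) or lower (left of 0) in KO, in full colour where camera called the list. Right, the median log2 ratio of each list's members, computed on CPM + 0.5, for KO 1 against the male WT 4 and for KO 2 against the mean of the female WT 1 to 3, with B-cell genes at 0.62 and 3.78.

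The interaction of genotype and sex asks whether the KO difference was the same in males and females. Trdc, the δ chain constant region, stood at 22 CPM in the male KO 1 and at 298 in the female KO 2, against 341 in the male WT and 302 to 310.2 in the WT females (difference of the log2 fold changes, male minus female, -3.92, adjusted p = 8.53e-29 by edgeR). Trbv13-1, a β chain V segment, was at 8.09 CPM in KO 1 and 710.3 in KO 2 against 12.3 in the male WT and 17.1 to 18.7 in the WT females (-5.92, adjusted p = 9.43e-28). Chd3, a chromatin remodeller, was at 56.3 and 461 CPM against 340 ± 20.6 (SD, n = 4) in WT (-3.20, adjusted p = 9.43e-28). In all, 7274 of 13294 genes passed. Each sex has 1 KO mouse and the male side 1 WT mouse, so the spread in this test came from the 3 WT females alone, and a difference between sexes cannot be told apart from a difference between the KO mice.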

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

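The V segments and their tests below were chosen after the values were seen, apart from the test on low-level genes, whose bounds were set before its result. Among the named genes without the sex-linked ones, 128 varied over the 4 WT libraries and were screened for a single WT library far from the others, by Dixon's ratio at its 5% critical value. Chance gives this in about 5% of groups, and 18 genes were picked out, in 15 of them because of WT 4, the one WT male. WT 4 was high for Hspa1b (217 CPM against a mean of 63.4 in the other 3), Fosb (46.4 against 34.6), Gfi1 (141 against 120.0), Pim1 (84.3 against 70.7), Ptpn13 (17.8 against 10.6), Gab2 (8.29 against 5.65), Cd79a (0.211 against 0.0856) and Cd22 (0.0351, 1 count, against 0). It was low for Gzma (188 against 245), Lig4 (67.5 against 84.6), Cflar (53.7 against 63.4), Cenpf (43.1 against 62.0), Trgv1 (37.5 against 46.1), Itgae (30.2 against 38.1) and Ccne1 (13.2 against 17.3). WT 1 stood apart for Dsg2 (0.0725 against 0) and Cdh5 (0.483 against 0.739), and WT 2 for H2-Aa (0.209 against 0.410).

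The genotype by sex interaction passed in 7274 genes and in 57 of the 134 named genes. Each value is the male minus the female log2 fold change, so it takes in the difference between KO 1 and KO 2 and that between WT 4 and the WT females. It was below 0 for H2-Aa (-11.18), Cd4 (-9.66), Cd74 (-7.33), Trbv13-1 (-5.92), Cxcr6 (-5.12), Cd79a (-4.68), Kit (-4.25), Trdc (-3.92), Cd44 (-3.21), Chd3 (-3.20), Lyz2 (-3.04), Cebpb (-2.31), Trac (-2.03), Rnf43 (-1.66), Cd8a (-1.36), Trbc1 (-1.22), Itgb7 (-0.98), Itgae (-0.91), Ptpn13 (-0.76), Oas1a (-0.74), Cd247 (-0.53), Ighm (-0.52), Ddit4 (-0.48), Trbc2 (-0.44), Oasl2 (-0.34), Tfrc (-0.32), Cd163l1 (-0.30), Epcam (-0.28) and Cdk6 (-0.22). It was above 0 for Casp8 (0.20), Hsph1 (0.22), Ddx21 (0.25), Tcf7 (0.28), Gzma (0.31), Cd3g (0.32), Lef1 (0.35), Cd5 (0.36), Ptcra (0.37), Il2ra (0.44), Ikzf3 (0.47), Cd3d (0.50), Ccne1 (0.55), Pdcd1 (0.57), Il9r (0.58), Anln (0.67), Rrm2 (0.69), Ccnb2 (0.73), Cenpf (0.75), E2f8 (0.79), Batf (0.80), Gimap4 (0.87), Cdkn1a (0.90), Cenpa (0.98), Tnfrsf19 (1.36), Pdgfrb (1.70), Lyl1 (2.77) and Cdkn2a (4.00). Some values rest on few counts. Cd4 had no count in KO 1, and against 3 counts its value is only known to be -4.70 or lower. KO 1 against WT 4 was lower by a ratio of 8.24 for H2-Aa (exact 95% interval 1.22 to 352), 1.14 for Cxcr6 (0.223 to 7.37), 12 for Cd44 (3.09 to 103) and 120 for Lyz2 (40.9 to 584), and higher by 508 for Cdkn2a (140 to 4200). In Lef1, Cd163l1, Gzma, Gimap4 and Hsph1 its sign was opposite to that of KO 1 against KO 2.

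The difference in Trbv13-1 belongs to a wider pattern: in each KO library a few T-cell receptor β V segments held most V counts. Trbv13-3 took 55.1% of 18783 V counts in KO 1 (95% Wilson interval 54.4 to 55.9) and Trbv13-1 took 48.3% of 19706 in KO 2 (47.6 to 49.0), while Trbv13-2 led in WT with 25.3 to 30.6%. Summed β V segments stood at 345 to 366 CPM in WT, 961 in KO 1 and 1470 in KO 2, so a lower share need not mean a lower level. Reads shared with near-identical relatives would have raised these too. In KO 2, Trbv13-2 was at 0.828 and Trbv13-3 at 1.70 times the WT mean, against 43.0 times for Trbv13-1, which argues against sharing there. In KO 1, Trbv13-2 was at 2.60 times the WT mean beside Trbv13-3 at 66.9 times, and shared reads cannot be told apart from use of both segments. A library made from few cells may also give this pattern: of 1092 genes at 1 to 3 CPM in WT, 4.95% were at 0 in KO 1 and at 0.5 times WT or more in KO 2, and 1.1% the other way, neither 20% or more in both directions nor under 2% in both, so few cells and clones that grew in each KO thymus (not tested) both stay open.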

How the results depend on the processing

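Each count was within 1.5 times its main value with size factors as in DESeq2, upper-quartile factors, no low-count filter, DESeq2, limma-voom, no sex term and thinned counts, and the median log2 fold change of all genes stayed between -0.124 and -0.016 there. At 5 CPM in 2 libraries, which tests fewer genes, 1303 genes changed at least 2-fold (642 lower). With weights per genotype, chosen after seeing the data, 1500 genes were called (987 higher, 513 lower; 65.8% higher against 46.1% in the main test), 1057 of them at least 2-fold (329 lower). 23 of the 139 named genes then lost their call. In females only, with the lone KO assumed to vary like WT, 8524 genes were called (4194 higher, 4330 lower), 1469 of them at least 2-fold higher. Leaving out 1 library gave 1665 to 9473 genes (881 to 4321 higher, 784 to 5152 lower), at least 2-fold 1161 to 4030 (629 to 1666 higher, 531 to 2364 lower). The low ends came without WT 1 or WT 2 (1714 genes; 1743 without WT 3) and the high ends without KO 2; 8279 genes were called without WT 4 and 8536 without KO 1. By construction the spread comes from WT alone without KO 1 or KO 2, and without WT 4 the male KO 1 is fitted by its own sex term. The genotype difference is then KO 1 against WT 4 alone without KO 2, and KO 2 against the WT females without KO 1. The cause of the low ends was not tested.

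WT and KO share the replicate numbers 1 and 2, but each library is a separate mouse, and no pairing was assumed in the main test. The deviations of same-numbered libraries from their group mean correlated at -0.148 and 0.029 across genes. With only 2 KO libraries these deviations mirror each other, so the correlations cannot tell whether the numbers pair libraries. With the replicate block in place of the sex term, which leaves 1 residual degree of freedom, 748 genes were called (413 higher, 335 lower), 730 of them at least 2-fold (404 higher, 326 lower), and 743 were among the main calls. Among the named genes, 40 lost their call with the block and 4, all Y-linked, turned direction. The block mixes sexes, and the Y-linked genes took log2 values of 10.66 (Eif2s3y), 12.01 (Uty), 8.89 (Ddx3y) and 10.70 (Kdm5d) in it. These come from near-zero counts in WT 1 and 2: the fold is at least 425 for Uty, and the ratio is 2050 for Eif2s3y (exact 95% interval 367 to 80900), 2110 for Kdm5d (377 to 83300) and 475 for Ddx3y (218 to 1300).

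Of the 21 called lists, 8 stayed past the threshold by camera in all 16 refits: T-cell identity, mature T-cell, β-selection, Wnt, progenitor, immediate-early, G2 and M-phase, and apoptosis genes. By fry, G2 and M-phase (0.066), S-phase (0.127), MYC (0.086) and interferon genes (0.066) lost their call. Calls of named genes were lost without a WT female for Cd247 (adjusted p up to 0.12), Cd74 (0.081), Cdh5 (0.0677), Cxcr6 (0.136), E2f8 (0.0574), Gfi1 (0.0624), H2-Aa (0.144), Ifng (0.0891), Pecam1 (0.112), Rrm2 (0.0643) and, without WT 3, Wdr43 (0.05 rounded), and for Cd74 without KO 2 (0.0615). With an estimated correlation 0 lists were called higher and 0 lower, but that run had little power with 3 residual degrees of freedom. Lists called higher numbered 8 to 19 when 1 library was left out, with 8 without KO 2, where double-positive (adjusted p 5.68e-22 without KO 1 to 0.762) and sort-gate genes (9.17e-10 to 0.79) turned direction. Dendritic-cell genes turned to a rise in females only (4.82e-08) and without WT 4 or KO 1 (1.8e-07 and 1.16e-07), against up to 0.988 with another library left out. Chd3 turned to 0.50 in females only and to 0.49 and 0.50 without WT 4 or KO 1, with a lowest value of -2.73 without KO 2. Without KO 2, log2 values turned to -0.20 (Cxcr6; highest 4.95), -2.95 (H2-Aa; 8.27), -7.37 (Cd4; 2.44), -0.51 (Trbc1; 0.73) and -0.62 (Trbv13-1; 5.33), the highest being without KO 1. The Cd4 value comes from 0 counts in KO 1, a fall of at least 4.8-fold against WT 4, and that of H2-Aa from 1 count, a ratio of 8.24 (1.22 to 352). These follow from the samples left, since KO 1 and KO 2 differ in these genes. The interaction count was 5048 with DESeq2 and 7002 to 7621 without a WT female.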

Other observations

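The genes and groups in this paragraph were chosen after their values were seen. Of 7 Hox genes tested, 6 fell, among them Hoxa5 (4.08 CPM in WT, 0 and 0.0746 in KO 1 and KO 2), Hoxa4 (1.98 CPM, 0 in both) and Hoxb4 (3.14 CPM, 0.205 and 0.224). The imprinted transcript H19 fell from 695 CPM in WT to 20.7 and 2.46 CPM (adjusted p = 0.0147 by edgeR), and its neighbour Igf2 from 4.80 to 0.307 and 0.896 CPM, while Igf2r rose from 106 to 311 and 217 CPM. Of 13 mitochondrially encoded protein genes, 12 fell, with a median log2 change of -1.37, and the share of counts from the mitochondrial genome was 2.61 to 2.92% in WT, 0.893% in KO 1 and 1.78% in KO 2. Of 81 ribosomal protein genes, 4 were called higher and 3 lower, with a median log2 change of 0.22 (range -3.03 to 1.23). In the Gimap family 6 of 8 rose and none fell. Large changes of like size in both KO libraries were seen in Agfg1 (107 CPM to 1175 and 1078), Ptpn14 (16.2 to 439 and 360), Adgre5 (6.64 to 375 and 370), P2rx7 (0.818 to 87.4 and 112) and Ppt1 (752 to 121 and 114).

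T-cell receptor α V segments, summed, stood at 31.2 to 35.8 CPM in WT, 33.9 in KO 1 and 210.0 in KO 2, where Trav14d-3-dv8 held 67.9% of 2819 counts (95% Wilson interval 66.1 to 69.6). In KO 1, Trav19 held 33.7% of 662 counts (30.2 to 37.4), and in WT Trav17 led with 22.6 to 25.6%.

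All tests and genes from here on were chosen after the values were seen. B-cell transcripts in KO 2 may come from B cells in the sort, which used no B-cell marker, although its CD25 gate should leave out most B cells. Of 16 B-cell genes under 1 CPM in WT, 15 were at least 5-fold higher in KO 2, with Cd74 at 359, H2-Aa at 108 and Igkc at 33.0 CPM, and 4, Cd22 among them, in KO 1. In KO 1 the ratio of Cd74 to Cd22 was 0.309 against 14.2 in KO 2, with Igkc at 0, which argues against B cells like those in KO 2 as the source of Cd22 there, and expression in the KO cells stays open. Part of the B-cell list (Ighm, Blk, Ly6d, Spib, Cd79b) is also expressed in WT DN3 cells, at 20.4 to 590 CPM.

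CD8 genes rose in cells sorted as CD8 negative. Double-positive thymocytes could bring Cd8a, but Cd4 was at 0 in KO 1 and at 1.50% of Cd8a in KO 2, which argues against them. One admixed cell type in both libraries would keep the ratios of Klf2, Gimap4, S1pr1 and Itgb7 to Cd8a alike, but these were 3.32 to 10.8 times higher in KO 1, so Cd8a and these genes did not rise in step. Immature CD8 single-positive cells cannot be told apart from CD8 transcription in the KO DN3 cells: Il2ra stood at 0.601 of the WT mean in KO 1 and 0.376 in KO 2, lower where Cd8a was higher, which fits both. A change of the KO cells themselves stays open as the genotype explanation and was not tested apart from these.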
